A study of Oryza sativa with 4 samples.

How the data were processed

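Per the labels' protocols, poly(A) RNA was ligated at the 5'-monophosphate of cleaved fragments, reverse transcribed with random primers, amplified and sequenced. Per the labels, the 4 libraries were a control and a heat library of each of 2 near-isogenic lines. The labels contradict one another: the tissue is given as seedlings and the treatment protocol describes potassium supply, while the series title and design name high night temperature at grain filling. That treatment is called heat throughout. The description of all 4 samples names small RNA, whereas the series title names a degradome and the tables hold degradome categories; the values were read as degradome reads. Groups were taken from the line and treatment labels. Reads of seed storage proteins made up 13% to 21% of the listed reads of a library, and those of photosynthesis genes 0.46% to 0.616%. These shares argue against green seedlings as the tissue, which was not otherwise checked.

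The authors deposited 4 pairwise tables, 1 for each comparison. Per the file headers, each gives raw read counts per library and normalized values, which the values show to be reads per 1000000 (RPM) of the summed listed reads. The totals behind them, recovered from the values, were 26293, 43001, 22730 and 31962 reads for sensitive control, sensitive heat, tolerant control and tolerant heat, so 1 read was worth 38, 23.3, 44 and 31.3 RPM. The deposited tables also give a degradome category and an alignment score for each site, a site p-value, and the authors' log2 fold change, p-value and q-value for each pair. CleaveLand is named per the file contents; the aligner, its version and the genome build are not given in the sources used here. Transcripts carry rice locus names or names of assembled transcripts. No genome was used here, so positions are nucleotides of a transcript as the files give them. Of 8364 loci, 0 were found in the reference gene table, so names are those of the files.

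Each library had the same reads in both of its tables (0 differences). Reads at 1 position shared by isoforms were spread about evenly over them (chi-square over degrees of freedom 1.06, 0.976, 1.0 and 0.989 in the order above). At 207 of 24479 transcript positions, different libraries name different miRNAs. Reads were therefore summed over isoforms and miRNAs that share the 8 bases on each side of the slice position of a gene, which turned 24686 pairs into 16080 merged sites; this step was chosen after seeing the data. The planned comparison of miRNA levels with target levels was not made, because the tables used here give degradome reads alone.

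Ratios compare RPM with exact conditional binomial intervals, levels have exact Poisson intervals and shares exact Clopper-Pearson intervals, all at 95% and all for counting error alone, since PCR copies are not independent molecules. A count of 0 was set to 3 reads and its ratio given at that floor, with the other count taken as exact. Higher and lower in the text mean that the interval excluded 1. Family lists were matched on miRNA name, gene description and ontology terms, and annotation lists on the description. Lists of families were scored by site and lists of annotations by gene, both with at least 10 reads in the 2 libraries together, a minimum chosen after seeing the data. Medians of lists with at least 3 members were ranked among 10000 random lists matched in 5 strata of level. There were 42 lists fixed before the data were examined, as were the comparisons and the rule for named genes. On simulated reads of the sensitive-line comparison, with 200 of 748 sites changed, intervals excluded 1 for 36% of sites changed 2-fold and 76% changed 4-fold, and for 4.2% and 4.01% of unchanged sites, with 0 changed sites in the wrong direction.

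The rule named, per comparison, the 8 target genes and 5 miRNAs with the highest and with the lowest ratio among pairs of category 0 to 2 with a q-value under 0.05 in the authors' deposited table, and up to 12 list members with the most reads. Other list members named in the text were chosen after their values were seen. Genes with at most 3 reads in both libraries have no ratio and were passed over. The reads given for such a gene are those of 1 merged site, unless all its sites are named. Since the authors' log2 values are infinite where 1 library has 0 reads, ratios of merged sites were ranked. The rule has no further read minimum where a call exists. With a minimum of 10 reads in 1 library, added after seeing the data, 3 of the 8 genes with the highest ratios between controls and 4 of the 8 between heat libraries were named again, and all 8 in each of the other 6 sets. Of the 5 miRNAs of a set, 2 to 5 were named again. Ranking zero counts at the floor, sums over all sites of a named gene, list ratios over all members or without the member with most reads, the scalings, the exact test and thinning were chosen after seeing the data. Alternatives included other categories, scores and read minimums, other scalings and an exact test on raw reads. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.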

Results

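Degradome sequencing reads the 5' ends of uncapped RNA fragments, among them the 3' products left when a microRNA (miRNA) guides cleavage of its target transcript. The 4 libraries came from rice near-isogenic lines that differ in heat tolerance, XN0437S (heat-sensitive) and XN0437T (heat-tolerant). Each line had a control and a heat library, the heat being high night temperature per the series title. Each of the 4 groups had 1 library, so no difference below has a replicate check. The deposited tables listed 7066 pairs of miRNA and transcript site in the sensitive control, 11357 in the sensitive heat library, 6544 in the tolerant control and 9598 in the tolerant heat library. Listed reads numbered 26290, 42996, 22728 and 31962 in the same order. These are reads at listed sites and not the sequencing depth, which is not known here. Between 60.1% and 63.6% of the pairs of a library had 1 read, and between 2.91% and 4.39% had a site p-value under 0.05 in the authors' deposited table. Ratios compare reads per 1000000 listed reads (RPM) and carry exact intervals of counting error alone at the 95% level. A ratio against 0 reads is computed at a floor of 3 reads per library, with the other count taken as exact. Its exact interval can therefore reach nearer to 1. Both alternative scalings below, by the median ratio of well-read sites and by totals without the storage and starch lists, were chosen after seeing the data. A summed ratio of a list is taken over its members with at least 10 reads in the 2 libraries together. The miRNA of a site is the one its table names, and with few site p-values under 0.05, reads at most sites are not shown to come from cleavage guided by it.

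Sites of known miRNA targets were listed for most families. Of 27 lists that pair a miRNA family with its known kind of target, 24 had at least 1 site and 23 had one in degradome categories 0 to 2, where the fragment end stands out on its transcript. The site of miR444 in the MADS-box gene LOC_Os02g36924, at nucleotide 753 of its transcript, had the most reads among the family sites: 1017 in the sensitive control, 2359 in sensitive heat, 1033 in the tolerant control and 1287 in tolerant heat. The miR168 site of argonaute 1A (LOC_Os02g45070), whose protein carries miRNAs in the silencing complex, lay at nucleotide 574 and had 145, 901, 181 and 758 reads in that order. Auxin response factor genes paired with miR160 together held 982, 1324, 628 and 819 reads. The miR166 sites of class III homeobox-leucine zipper genes, regulators of leaf polarity, held 220, 670, 282 and 538 reads. NAC genes paired with miR164 held 344, 953, 385 and 637 reads. The lists for miR395, miR2118 and miR5179 had 0 sites, and those for miR397, miR399, miR827, miR390 and miR172 had at most 9 reads in any library. Several of these sites have the same bases in other listed genes (3 for LOC_Os10g33940 under miR160, 1 for argonaute 1A), and their reads cannot be assigned to 1 gene with certainty. The same holds for LOC_Os11g01872 and the inhibitor at LOC_Os07g11630 (1 other gene each), LOC_Os11g17970 (2) and LOC_Os06g01620 (3), named further on.

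**Figure D1:**
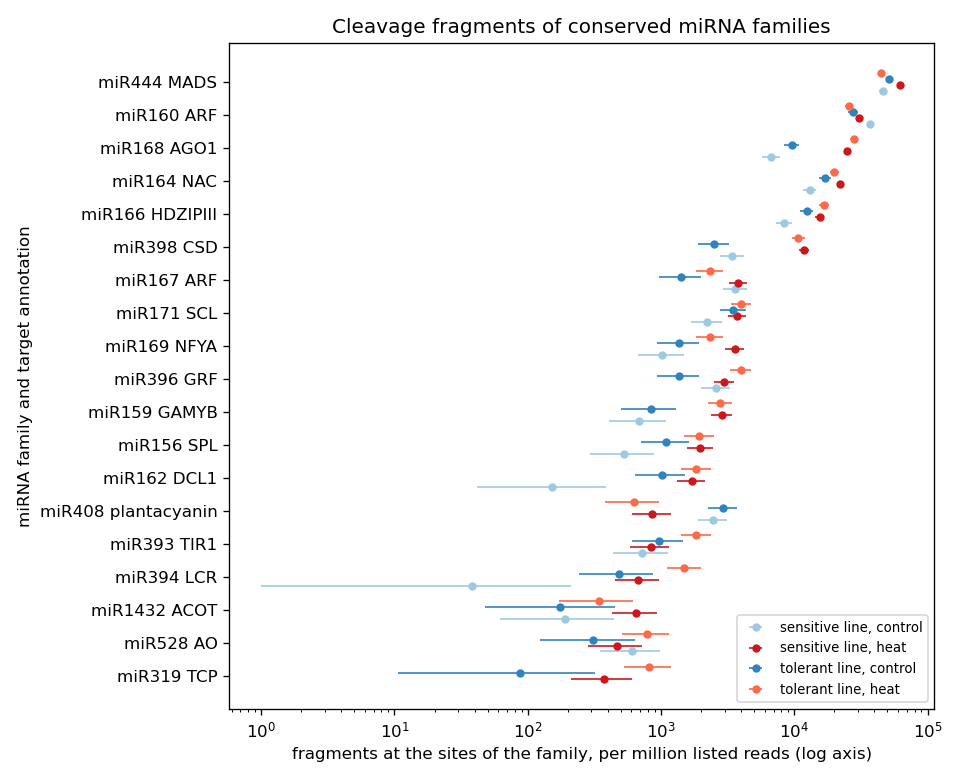
Reads at the sites of each miRNA family list with at least 30 reads over the 4 libraries, as RPM of listed reads on a log axis, with points for the 4 libraries (light blue and blue for sensitive and tolerant control, red and orange for sensitive and tolerant heat) and bars for exact Poisson intervals; a library with 0 reads has no point. The miR168 sites held 176 and 217 reads in the controls and 1076 and 890 in heat.

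The comparison of sensitive heat with sensitive control asked which cleavage sites differ under heat in the heat-sensitive line. Fragments of heat-shock genes were higher in heat: summed over the list, the ratio was 1.94 (1.73 to 2.18). Among heat-shock genes with at least 10 reads, 12 of 26 members were higher, 2 were lower and 12 had an interval that held 1. A mitochondrial small heat shock protein (LOC_Os02g52150) had 93 reads against 0, a ratio of 19 at the floor, and the class I small heat shock genes at LOC_Os03g15960 had a ratio of 20.8 (5.54 to 175). The heat shock cognate gene LOC_Os03g16920 had a ratio of 6.4 (3.76 to 11.7), while BIP1 (LOC_Os02g02410), a chaperone of the endoplasmic reticulum, had 1.17 (0.963 to 1.42) and the stromal chaperone LOC_Os12g14070 was lower at 0.519 (0.341 to 0.787).

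Genes of the small RNA pathway were higher together, with 5 of 5 members higher and a summed ratio of 3.96 (3.38 to 4.66). Argonaute 1A had a ratio of 3.8 (3.19 to 4.56), argonaute 1B (LOC_Os04g47870) 2.79 (1.8 to 4.49), and Dicer-like protein 1 (LOC_Os03g02970), which processes miRNA precursors, 11.8 (4.42 to 44.3) with 77 reads against 4. This list holds the miR168 and miR162 targets. Cell wall genes were higher, at 4.69 (2.56 to 9.4), with 3 of 5 members higher, 0 lower and 2 whose interval held 1, and 4.2 (1.99 to 10.2) without the expansin-like gene LOC_Os10g39640. The miR398 targets were also higher, with a summed ratio of 3.43 (2.74 to 4.34). The site in LOC_Os07g46990, annotated with superoxide dismutase activity, had 395 reads against 68, and the copper chaperone of superoxide dismutase LOC_Os04g48410 had 61 reads against 18. The miR159 site of GAMYB (LOC_Os01g59660), a transcription factor of gibberellin signalling, had a ratio of 4.24 (2.54 to 7.53), and the miR394 site of the F-box gene LOC_Os01g69940 had 29 reads against 1. The miR160 targets had a summed ratio of 0.823 (0.757 to 0.894), with 1 site higher, LOC_Os06g47150 at 1.32 (1.15 to 1.53), and 3 lower, among them LOC_Os02g41800 at 0.395 (0.314 to 0.494). Growth-regulating factor genes under miR396 had 1.14 (0.832 to 1.57), with 1 of 6 sites higher, 2 lower and 3 whose interval held 1. Auxin genes, which include the miR160 targets, had 0.849 (0.784 to 0.919), or 0.95 (0.858 to 1.05) without the gene with most reads. The blue copper protein LOC_Os08g37670, a miR408 target, had 28 reads against 55 at its main site. The miR408 list had a summed ratio of 0.348 (0.226 to 0.529) over 2 sites, both in this gene. Without the site with most reads, a check added after seeing the data for every list, the ratios of the miR160 and miR408 lists were 0.92 (0.823 to 1.03) and 0.55 (0.198 to 1.51), and both intervals held 1.

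Genes of seed storage proteins held 16.2, 13.4, 21 and 13% of the listed reads in sensitive control, sensitive heat, tolerant control and tolerant heat, and photosynthesis genes 0.46, 0.616, 0.563 and 0.535%. The starch list had a summed ratio of 0.34 (0.32 to 0.361), with 1 of 14 members higher, 6 lower and 7 whose interval held 1, and most of its reads lay in inhibitors of amylase and trypsin, which are seed defence and allergen proteins and not enzymes of starch synthesis; 1 seed allergen locus of this list is also in the storage list. The inhibitor at LOC_Os07g11630 had 720 reads against 1997, and without it the ratio of the list was 0.59 (0.538 to 0.646). Among enzymes of the list, branching enzyme LOC_Os02g32660 had a ratio of 0.175 (0.0891 to 0.322), granule-bound starch synthase LOC_Os06g04200 0.44 (0.226 to 0.84) and soluble starch synthase LOC_Os06g06560 1.51 (0.768 to 3.12). Among storage-protein genes, 3 of 14 members were higher, 8 were lower and 3 had an interval that held 1, and the summed ratio was 0.83 (0.798 to 0.864). A type B glutelin (LOC_Os02g15070) had a ratio of 0.45 (0.385 to 0.524) and the globulin-like gene LOC_Os03g46100 1.53 (1.41 to 1.67). The amyloplast transporter BT1 (LOC_Os02g10800), which brings sugar nucleotides into starch-forming plastids, had a ratio of 0.415 (0.362 to 0.476). Photosynthesis genes, the list for green tissue, had 1 of 10 members higher and 0 lower, with a summed ratio of 1.26 (0.999 to 1.6), or 1.34 (1.08 to 1.67) over all members and 1.56 (1.15 to 2.14) without the member with most reads.

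By the fixed rule, which ranks single sites, the highest ratio lay in LOC_Os11g01872, annotated as a regulatory-associated protein of TOR, with 604 reads against 1 at nucleotide 4195 and a ratio of 369 (66 to 14611). Its lowest site p-value in the authors' deposited table was 0.996. That of the Myb-like gene LOC_Os03g38210 was 0.00484. High ratios also came from a site of this Myb-like gene (53 reads against 2), the membrane protein gene LOC_Os07g24000 (49 reads against 2), the outer envelope gene LOC_Os02g48480 (56 reads against 0) and nucleotide 572 of an uncharacterized gene at LOC_Os09g00999 (54 reads against 0). The lowest ratios were in a ribosomal protein gene (LOC_Os02g14059, 2 reads against 34), an RNA-directed DNA methylation gene (LOC_Os05g43060, 1 read against 16), an RNA-binding protein gene (LOC_Os01g41880, 1 read against 15), the dioxygenase gene LOC_Os04g39980 (1 read against 14) and the phospholipase gene LOC_Os07g33670 (1 read against 12). Low ratios also came from LOC_Os05g33570 (1 read against 11), the splicing factor gene LOC_Os05g48960 (1 read against 10) and the bZIP gene LOC_Os07g08420 (1 read against 10). Over all listed sites of each gene, 8 of the 8 genes named for the highest ratios were higher and 7 of the 8 named for the lowest were lower. Each sum includes the site that named the gene, which for some genes holds all the reads. These counts are therefore no separate check. The outer envelope gene had 67 reads against 15 over all sites, LOC_Os09g00999 374 reads against 109, the dioxygenase gene 76 reads against 72 and the bZIP gene 29 reads against 20, with an interval that held 1 for the last. Target reads were also summed over the sites paired with each miRNA, which gives no miRNA levels. Sites of a variant of miR1436 had 695 reads against 14, of which the site of LOC_Os11g01872 gave 604 reads against 1. The miR162 site had 73 reads against 4, and sites of a variant of miR1861 had 24 reads against 187. Of 748 merged sites with at least 10 reads, 176 were higher, 146 lower and 426 had an interval that held 1. Higher sites were 54.7% of those whose interval excluded 1, 54.1% with median-ratio scaling and 48.3% with totals without the storage and starch lists. Without the 10-read minimum, itself chosen after seeing the data, the shares were 33.7%, 33.4% and 25.6%. Listed totals were 43001 reads in sensitive heat and 26293 in the sensitive control. At unequal totals, fewer reads suffice to exclude 1 in favour of the library with the smaller total. Shares without a read minimum are tilted by this and do not give the balance of directions. Of the 15917 pairs listed, 2506 (15.7%, exact binomial interval 15.2 to 16.3%) had reads in both libraries. The authors' deposited table gave a q-value under 0.05 to 14918 pairs, 9416 higher and 5502 lower, and 9165 of these rested on a single read. An exact test on the reads of merged sites with Benjamini-Hochberg adjustment, which compares these 2 libraries and not the conditions, called 144 of 10667 sites, 61 higher and 83 lower.

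Tolerant heat against tolerant control put the same question to the heat-tolerant line. Heat-shock genes were again higher in heat, at a summed ratio of 2.67 (2.32 to 3.07), with 16 of 24 members higher, 1 lower and 7 whose interval held 1. LOC_Os02g52150 had 79 reads against 0, BIP1 had a ratio of 2.46 (1.91 to 3.2), and LOC_Os04g01740, a heat shock protein, had 30 reads against 0. As in the sensitive line, cell wall genes were higher, at 4.78 (2.9 to 8.34), with 4 of 6 members higher, 0 lower and 2 whose interval held 1, led by LOC_Os10g39640 at 15.2 (4.96 to 75.5). Without that gene the ratio was 2.7 (1.51 to 5.14). The starch list was lower, at 0.381 (0.354 to 0.409), with 1 of 12 members higher, 8 lower and 3 whose interval held 1. Storage proteins were lower, at 0.621 (0.596 to 0.648), with 2 of 13 members higher, 10 lower and 1 whose interval held 1.

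The amylase inhibitor LOC_Os07g11310 had 106 reads against 547 and the inhibitor at LOC_Os07g11630 a ratio of 0.502 (0.454 to 0.556). Branching enzyme LOC_Os02g32660 had 0.147 (0.0499 to 0.361), whereas soluble starch synthase LOC_Os06g06560 was higher at 4.15 (1.73 to 12.1). Glutelin LOC_Os02g15070 had a ratio of 0.312 (0.266 to 0.364), prolamin LOC_Os07g10570 0.255 (0.171 to 0.375) and transporter BT1 0.312 (0.259 to 0.376). All 5 small RNA pathway genes tested were higher, with a summed ratio of 2.82 (2.45 to 3.27): argonaute 1A had 2.98 (2.53 to 3.52) and Dicer-like protein 1 1.76 (1.09 to 2.93). Its miR162 site had 1.82 (1.11 to 3.1), or 1.55 (0.941 to 2.62) with totals without the storage and starch lists. The 3 miR398 sites tested were higher, at 4.29 (3.24 to 5.79). The miR408 list was lower, at 0.216 (0.124 to 0.36). Without the main site of LOC_Os08g37670, the only gene of that list, the other site of the gene had 0.905 (0.382 to 2.2). Growth-regulating factor genes under miR396 had a summed ratio of 2.73 (1.81 to 4.22), with 3 of 6 sites higher, 0 lower and 3 whose interval held 1, and GAMYB had 3.29 (1.99 to 5.73). The single miR394 site tested was higher, at 3.1 (1.59 to 6.63). The miR160 targets had 0.925 (0.833 to 1.03) and auxin genes 0.975 (0.881 to 1.08), whose median log2 ratio had the other sign, 0.50. Median-ratio scaling turned these 2 ratios to 1.21 (1.09 to 1.35) and 1.28 (1.16 to 1.42). Totals without the storage and starch lists gave 0.784 (0.706 to 0.872) and 0.826 (0.747 to 0.914), and leaving out LOC_Os06g47150, with most reads in both lists, 0.686 (0.597 to 0.788) and 0.777 (0.684 to 0.884). Photosynthesis genes had a summed ratio of 0.803 (0.609 to 1.06), which median-ratio scaling turned to a log2 ratio of 0.076. It was 0.635 (0.438 to 0.918) without the member with most reads and 0.68 (0.516 to 0.898) with totals without the storage and starch lists.

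The same rule again put the site of LOC_Os11g01872 first, with 306 reads against 4. It was followed by sites in genes that included selenium-binding protein LOC_Os01g68770 (95 reads against 3), LOC_Os04g46892 (48 reads against 2), calcyclin-binding protein LOC_Os01g55270 (21 reads against 1), the peptide transporter family gene LOC_Os11g17970 (20 reads against 1), LOC_Os01g11550 (18 reads against 1) and EXORDIUM (LOC_Os02g52010, 17 reads against 1). Lower in heat were a ubiquitin-conjugating enzyme (LOC_Os04g57220, 1 read against 35), a putative sodium-proton antiporter (LOC_Os09g11450, 1 read against 19), a homolog of MOTHER of FT and TFL1 (LOC_Os06g30370, 1 read against 12), a vacuolar processing enzyme (LOC_Os02g43010, 1 read against 10), a late embryogenesis abundant protein (LOC_Os08g23870, 1 read against 10) and LOC_Os12g23280 (2 reads against 20). Over all listed sites of each gene, 8 of the 8 genes named for the highest ratios were higher and 8 of the 8 named for the lowest were lower. As before, the sums include the naming sites, for some genes with all the reads, and are no separate check. The chromosome maintenance gene LOC_Os05g51790, paired with miR1861, had 6 reads against 55 here and 19 reads against 183 in the sensitive line. Sites paired with the variant of miR1436 had 351 reads against 15, of which the site of LOC_Os11g01872 gave 306 reads against 4. Sites paired with a variant of miR535 had 0 reads against 16. Of 575 merged sites with at least 10 reads, 145 were higher, 136 lower and 294 had an interval that held 1. Higher sites were 51.6% of those whose interval excluded 1, 66.7% with median-ratio scaling and 43.3% with totals without the storage and starch lists. Without the 10-read minimum, itself chosen after seeing the data, the shares were 47.4%, 70.0% and 28.7%, which unequal totals can tilt as in the sensitive line. Of the 14053 pairs listed, 2089 (14.9%, exact binomial interval 14.3 to 15.5%) had reads in both libraries. The authors' deposited table gave a q-value under 0.05 to 13273 pairs, 7997 higher and 5276 lower, and 8534 of these rested on a single read. An exact test on the reads of merged sites with Benjamini-Hochberg adjustment, which compares these 2 libraries and not the conditions, called 120 of 9710 sites, 57 higher and 63 lower.

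**Figure D2:**
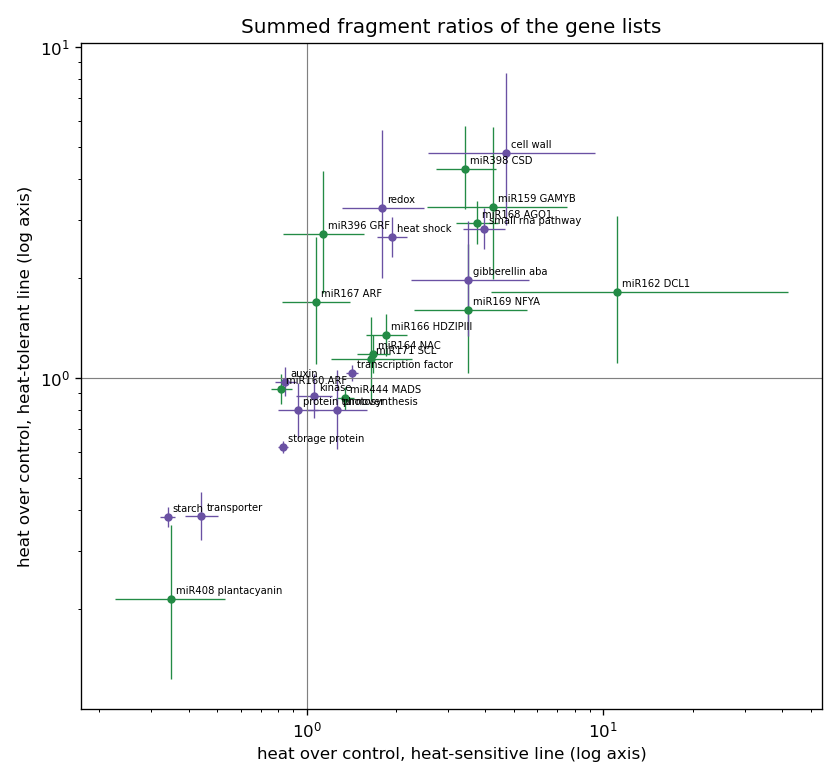
Ratio of heat over control summed over each list, in the heat-sensitive line (horizontal) and the heat-tolerant line (vertical), both on log axes, for lists with at least 60 reads in each comparison. Green points are miRNA family lists, purple points are annotation lists and bars are exact counting intervals; heat shock, miR398 and the small RNA pathway lie above 1 on both axes, and starch and miR408 below 1 on both.

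Between the lines without heat, tolerant control was set against sensitive control. Storage-protein genes were higher in the tolerant line, at 1.3 (1.25 to 1.35), with 9 of 13 members higher, 1 lower and 3 whose interval held 1. Auxin genes were lower, at 0.711 (0.644 to 0.784), with 0 of 7 members higher, 5 lower and 2 whose interval held 1. This list contains miR160 targets, at 0.74 (0.668 to 0.819), and miR167 targets, at 0.386 (0.248 to 0.585). The miR162 site of Dicer-like protein 1 had 23 reads against 4 and the miR394 site of LOC_Os01g69940 had 11 reads against 1.

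Glutelin LOC_Os02g15070 had a ratio of 1.53 (1.34 to 1.75) and amylase inhibitor LOC_Os07g11310 2.51 (2.16 to 2.93), while the inhibitor at LOC_Os07g11630 was lower at 0.537 (0.496 to 0.581). Heat-shock genes had a summed ratio of 0.774 (0.658 to 0.91), with 3 of 15 members higher, 2 lower and 10 whose interval held 1. BIP1 had 80 reads against 164, and without it the ratio was 0.933 (0.76 to 1.14), with an interval that held 1. The miR396 targets had 0.479 (0.284 to 0.783), with 0 of 5 sites higher, 2 lower and 3 whose interval held 1. The small RNA pathway had 1.54 (1.26 to 1.88), with 2 of 4 members higher, 0 lower and 2 whose interval held 1, and photosynthesis genes 1.2 (0.902 to 1.61), or 1.53 (1.04 to 2.27) without the member with most reads. The starch list had 0.851 (0.805 to 0.90), with 3 of 12 members higher, 1 lower and 8 whose interval held 1, and turned to 1.51 (1.39 to 1.65) without the inhibitor at LOC_Os07g11630. Sites with high ratios by the rule rested on few reads: nucleotide 974 of glucose and ribitol dehydrogenase LOC_Os05g04870 had 19 reads against 1, carboxylesterase LOC_Os07g06830 9 reads against 1, LOC_Os11g43900 8 reads against 1, alpha-glucosidase LOC_Os06g46284 15 reads against 2 and LOC_Os06g01620, a miR171 site of category 0, 7 reads against 1. Lower in the tolerant line were LOC_Os12g31790 (1 read against 34), dihydroneopterin aldolase LOC_Os08g44210 (1 read against 22), phenylalanine ammonia-lyase LOC_Os02g41630 (1 read against 16), LOC_Os04g32030 (8 reads against 119), the bZIP gene LOC_Os05g36160 (1 read against 12, with bases found in 164 other genes) and embryonic protein LOC_Os02g15250 (1 read against 11). Over all listed sites of each gene, 5 of the 8 genes named for the highest ratios were higher and 6 of the 8 named for the lowest were lower. Here too the sums include the naming sites and are no separate check. The intervals of LOC_Os07g06830, LOC_Os11g43900, LOC_Os06g01620 and LOC_Os05g36160 held 1, and the MADS-box gene LOC_Os02g36924, named for 1 read against 10 at nucleotide 748, was higher as a whole at 1.15 (1.06 to 1.25). Of 495 merged sites with at least 10 reads, 72 were higher, 75 lower and 348 had an interval that held 1. Higher sites were 49% of those whose interval excluded 1, 37.8% with median-ratio scaling and 53.7% with totals without the storage and starch lists. Without the 10-read minimum, itself chosen after seeing the data, the shares were 48.8%, 33.3% and 57.7%, which unequal totals can tilt as described above. Of the 11631 pairs listed, 1979 (17%, exact binomial interval 16.3 to 17.7%) had reads in both libraries. The authors' deposited table gave a q-value under 0.05 to 10974 pairs, 5227 higher and 5747 lower, and 6939 of these rested on a single read. An exact test on the reads of merged sites with Benjamini-Hochberg adjustment, which compares these 2 libraries and not the conditions, called 40 of 7848 sites, 19 higher and 21 lower.

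The lines were also compared under heat, tolerant against sensitive. Heat-shock genes had a summed ratio of 1.06 (0.974 to 1.15), with 23 of 29 members whose interval held 1, the small RNA pathway 1.11 (1.02 to 1.21) and storage proteins 0.972 (0.934 to 1.01), whose median log2 ratio had the other sign, 0.089, as had their sum with median-ratio scaling, at a ratio of 1.11 (1.07 to 1.16). That scaling gave 1.21 (1.11 to 1.32) for heat-shock genes. Without the member with most reads, storage proteins had 0.92 (0.874 to 0.967) and the small RNA pathway 1.02 (0.846 to 1.24). The miR444 targets were lower in the tolerant line, at 0.718 (0.673 to 0.766), as were the miR160 targets at 0.832 (0.762 to 0.909), the miR167 targets at 0.611 (0.458 to 0.809) and the miR169 targets at 0.632 (0.469 to 0.845), subunits of a CCAAT-binding factor. With median-ratio scaling the miR160 targets had 0.952 (0.871 to 1.04), with an interval that held 1. The auxin receptor genes under miR393 were higher, at 2.2 (1.43 to 3.44), and so was the single miR394 site tested, at 2.23 (1.38 to 3.66). Without the site with most reads, the ratios of the miR167, miR169 and miR393 lists were 0.745 (0.482 to 1.14), 0.888 (0.563 to 1.39) and 1.35 (0.63 to 2.87), and all 3 intervals held 1. Auxin genes had 0.817 (0.752 to 0.888), or 0.935 (0.86 to 1.02) with median-ratio scaling. Cell wall genes were higher, at 1.66 (1.27 to 2.18), with 2 of 7 members higher, 0 lower and 5 whose interval held 1, but had 1.28 (0.891 to 1.85) without LOC_Os10g39640. The starch list had 0.953 (0.884 to 1.03), with 1 of 15 members higher, 5 lower and 9 whose interval held 1; median-ratio scaling turned it to 1.09 (1.01 to 1.18), and without the inhibitor at LOC_Os07g11630 it had 0.743 (0.666 to 0.829). Photosynthesis genes had 0.86 (0.696 to 1.06), with all 12 member intervals holding 1, and 0.768 (0.588 to 0.996) without the member with most reads.

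By the rule, a site of aldehyde dehydrogenase LOC_Os02g49720 had 12 reads against 1, nucleotide 2478 of the uncharacterized gene at LOC_Os09g00999 53 reads against 5, nucleotide 778 of LOC_Os05g04870 10 reads against 1 at bases shared with 10 other genes, LOC_Os04g58280 9 reads against 1, the basic helix-loop-helix gene LOC_Os01g13460 8 reads against 1 and PCF6 (LOC_Os03g57190), a miR319 target, 8 reads against 1. Lower were sites in small heat shock gene LOC_Os11g13980 (1 read against 20), LOC_Os07g20340 (1 read against 17), isocitrate lyase LOC_Os07g34520 (1 read against 17), an abscisic-acid-inducible gene (LOC_Os04g52110, 2 reads against 30), a homeobox gene (LOC_Os05g47820, 1 read against 14) and salt stress protein LOC_Os01g13210 (1 read against 12). Over all listed sites of each gene, 5 of the 8 genes named for the highest ratios were higher and 7 of the 8 named for the lowest were lower. Again the sums include the naming sites and are no separate check. The intervals of LOC_Os05g33570, LOC_Os02g49720, LOC_Os05g04870 and LOC_Os01g13210 held 1. The small heat shock gene had 17 reads against 48 over all sites, a ratio of 0.476 (0.257 to 0.844), LOC_Os09g00999 1248 reads against 374 and LOC_Os05g04870 31 reads against 40; at nucleotide 974 the last had 8 reads against 18. Of 793 merged sites with at least 10 reads, 100 were higher, 101 lower and 592 had an interval that held 1. Higher sites were 49.8% of those whose interval excluded 1, 61% with median-ratio scaling and 49.8% with totals without the storage and starch lists. Without the 10-read minimum, itself chosen after seeing the data, the shares were 58.8%, 80.4% and 58.8%. Unequal totals tilt these shares as described above, here towards the tolerant library, which has the smaller total. Of the 17678 pairs listed, 3277 (18.5%, exact binomial interval 18 to 19.1%) had reads in both libraries. The authors' deposited table gave a q-value under 0.05 to 16156 pairs, 7286 higher and 8870 lower, and 10256 of these rested on a single read. An exact test on the reads of merged sites with Benjamini-Hochberg adjustment, which compares these 2 libraries and not the conditions, called 46 of 12034 sites, 27 higher and 19 lower.

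The signs of heat differences were compared between the 2 lines. Of 5284 pairs listed in both heat comparisons, 3132 (59.3%, 57.9 to 60.6%) had the same sign, against 50.9% for independent signs with the shares of higher and lower pairs found here, a reference added after seeing the data. Another 10633 and 8769 pairs were listed in the sensitive or the tolerant comparison alone. Both comparisons listed 3524 genes and 490 miRNAs, against 3156 and 478 in both line comparisons. Among merged sites with at least 10 reads in each comparison, 320 of 443 (72.2%, against 50.0%) had the same sign, with a correlation across sites of 0.55 (Pearson) and 0.56 (Spearman); sites are not independent replicates. Of these, 68 were higher in both lines, against 30.3 for independent lists, and 64 lower in both, against 25.3. Argonaute 1A, GAMYB, LOC_Os07g46990 and LOC_Os11g01872 were among the sites above 1 in both, and LOC_Os05g51790 and LOC_Os08g37670 among those below. For the line difference, 2353 of 4623 pairs (50.9%, 49.4 to 52.3%) had the same sign in control and heat, against 49.9% for independent signs, and 185 of 363 merged sites (51%, against 49.2%), with a correlation across sites of 0.021 (Pearson) and 0.031 (Spearman). Neither pair of comparisons shares a library, and whether the lines differ in their response was not tested.

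Against 10000 random lists of the same size and level, the median of the heat-shock list lay at percentile 99.8 in the sensitive line and 99.8 in the tolerant line under heat. The small RNA pathway lay at 99.9 and 94.3, miR168 targets at 99.8 and 93.6, and miR398 targets at 97.6 and 94.3. The starch list lay at 6.8 and 0.35, storage proteins at 10.4 and 2.88, and cell wall genes at 79.4 and 99. Without heat, storage proteins lay at 97.8 and auxin genes at 1.35. Neither list stayed outside the central 95% with unmatched random lists or with members of more than 3 reads in 1 library. In all, 4 of 22 lists lay outside the central 95% in the sensitive line under heat, 3 of 22 in the tolerant line, 2 of 19 between controls and 0 of 24 between heat libraries. Lists overlap and are not independent. In sensitive heat, argonaute 1A gave 901 of 1072 reads of the miR168 list and 902 of 1158 of the small RNA pathway list.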

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

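Results stood out where an effect had opposite signs in the 2 lines or the 2 treatments, with both counting intervals excluding 1; with 1 library per group none of these differences was tested. Merged sites, both scalings and sums without the member with most reads were chosen only after the result was seen. Heat ratios in the sensitive and the tolerant line were, for the miR444 list, 1.35 (1.26 to 1.44) and 0.869 (0.803 to 0.94), a quotient of 1.55, although its median site had a log2 ratio of -1.71 in the sensitive line, and for its main site in LOC_Os02g36924 1.42 (1.32 to 1.53) and 0.886 (0.816 to 0.963), a quotient of 1.6. At nucleotide 974 of dehydrogenase LOC_Os05g04870 they were 11 (1.74 to 459) and 0.299 (0.113 to 0.716), a quotient of 36.8, or 2.43 between the nearest ends of both intervals. Nucleotide 384 of late embryogenesis gene LOC_Os08g23870 had 0 and 10 reads in sensitive control and heat and 10 and 1 in tolerant control and heat. Its ratio was 2.04 at the floor in the sensitive line, with an exact interval from 1.37, and 0.0711 (0.00164 to 0.50) in the tolerant line. With the 0 reads set to the floor the quotient is 28.7, which is not a bound because the second ratio rests on 1 read, and between the nearest ends of both intervals it is 2.74. Quotients at the interval ends were added after seeing the data.

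Line ratios in control and in heat were 0.479 (0.284 to 0.783) and 1.3 (1.01 to 1.68), a quotient of 0.367, for the miR396 targets, and 1.15 (1.08 to 1.22) and 0.829 (0.793 to 0.866), a quotient of 1.38, for transcription factors. The second list holds the miR444 site of LOC_Os02g36924, and 38 of 48 and 55 of 65 of its members had intervals that held 1. Without the genes of the miR444 list, a check added after seeing the data, its ratios were 1.18 (1.09 to 1.29) and 0.942 (0.887 to 1.0), so the second interval narrowly held 1. At nucleotide 178 of the inhibitor at LOC_Os07g11630 the line ratios were 0.43 (0.368 to 0.503) and 1.36 (1.13 to 1.65), a quotient of 0.316. The miR444 list had 1.11 (1.03 to 1.21) and 0.718 (0.673 to 0.766), a quotient of 1.55, and its site in LOC_Os02g36924 1.17 (1.08 to 1.28) and 0.734 (0.685 to 0.786), a quotient of 1.6. LOC_Os08g23870 had 3.86 at the floor in control, with an exact interval from 2.59, and 0.135 (0.0031 to 0.946) in heat. Its quotient at the floor is the 28.7 given above, since it is made of the same 4 libraries. Without nucleotide 753 of LOC_Os02g36924, the miR444 list had heat ratios of 0.959 (0.797 to 1.16) and 0.728 (0.565 to 0.939) and line ratios of 0.791 (0.628 to 0.994) and 0.588 (0.474 to 0.726). Only this position was left out and not the whole gene. In the sensitive control it held 1017 reads, and all listed sites of the gene held 1154. Without its site with most reads, the miR396 list had a line ratio of 1.2 (0.882 to 1.63) in heat.

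With median-ratio scaling the opposite signs of several of these ended. Heat ratios became 1.34 (1.25 to 1.44) and 1.14 (1.06 to 1.23) for the miR444 list and 1.41 (1.31 to 1.52) and 1.16 (1.07 to 1.26) for its site in LOC_Os02g36924, above 1 in both lines. In control, line ratios became 0.969 (0.893 to 1.05) for the list, 1.02 (0.935 to 1.11) for the site and 0.995 (0.938 to 1.06) for transcription factors, and that of LOC_Os08g23870 in heat became 0.154 (0.00355 to 1.08); all 4 intervals held 1. The opposite heat effects of LOC_Os05g04870 and LOC_Os08g23870 and the opposite line effects of the miR396 list and the inhibitor at LOC_Os07g11630 kept both intervals away from 1 with this scaling, and all effects did with totals without the storage and starch lists.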

How the results depend on the processing

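No paired analysis was possible because each group has 1 library, so no comparison of 2 groups has more than 1 pair. For the same reason none could be left out. A heat effect over both lines with the line as a block, which leaves 1 residual degree of freedom, was not among the comparisons and was not run. Scalings, intervals and the exact test on merged sites, thinning, lists with other members (more than 3 reads in 1 library, no minimum, no miR444 genes, no most-read member) and same-sign shares of sites with 1 or 30 reads were chosen after seeing the data. The planned share of pairs with opposite signs of miRNA and target was not run. Values stand in the order sensitive line under heat, tolerant line under heat, lines in control, lines in heat. Stricter filters and coarser units leave fewer items to count, and unequal library totals tilt the shares of higher sites where no read minimum is set. The cause of other shifts was not tested. Listed pairs numbered 15917, 14053, 11631 and 17678. They numbered 648, 658, 528 and 701 in categories 0 and 1, 382, 357, 285 and 385 in category 0, 447, 496, 398 and 479 with a site p-value under 0.05, 1183, 1117, 882 and 1330 with a score of at most 4, 1347, 1108, 878 and 1398 with 5 reads and 583, 469, 378 and 573 with 10 reads. Counting miRNA and gene gave 10526 in the sensitive line. Merged positions, dropping predicted miRNAs and thinning stayed within 1.5 times.

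Pairs called by the authors' deposited table numbered 14918, 13273, 10974 and 16156. They numbered 4498, 3770, 3196 and 4718 in categories 0 to 2 and 552, 444, 346 and 485 with 10 reads in 1 library, or 6036, 5602, 4696 and 6583 as genes and 527, 522, 501 and 537 as miRNAs. Thresholds on log2 change, p-value or pseudocount stayed within 1.5 times. The exact test called 144, 120, 40 and 46 merged sites. Intervals excluded 1 at 700, 437, 320 and 410 merged sites, at 698, 443, 276 and 571 with median-ratio scaling and at 695, 508, 284 and 410 with totals without the storage and starch lists. The higher ones made up 33.7, 47.4, 48.8 and 58.8%, 33.4, 70.0, 33.3 and 80.4%, and 25.6, 28.7, 57.7 and 58.8%. These scalings moved every log2 ratio by -0.0035, 0.39, -0.20 and 0.19, and by -0.18, -0.24, 0.055 and -0.0076.

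Lists outside the central 95% numbered 2 between controls, 1 with category 0 to 2 members, 0 with unmatched random lists and 1 with more than 3 reads in 1 library. The last was neither of the first 2. Between heat libraries they numbered 0, 2 with that lower minimum and 1 with totals without the storage and starch lists. In the heat comparisons their number stayed within 1.5 times. In the sensitive line, 3 of the 4 lists stayed outside with category 0 to 2 members, unmatched random lists and the lower minimum each. With category 0 to 2 members, 5 lists lay outside there, 3 higher and 2 lower. All 4 stayed outside with both scalings. In the tolerant line all 3 stayed outside in each alternative. Summed log2 ratios reversed with median-ratio scaling for miR444 targets (0.19 against -0.20) and protein turnover (0.070 against -0.32) in the tolerant line, and for miR444 targets (-0.046 against 0.16) and transcription factors (-0.0069 against 0.20) between controls. Kinases between controls reversed with the lower minimum (-0.021 against 0.27). Without the member with most reads, reversals were miR444 targets in the sensitive line (-0.060 against 0.43) and between controls (-0.34 against 0.16), gibberellin and abscisic acid genes (-1.12 against 0.98) and transporters (0.43 against -1.38) in the tolerant line, starch between controls (0.60 against -0.23) and transporters in heat (0.64 against -0.42). The same-sign share of heat differences was 59.3%, and 61.6% for called pairs, 72.2% for sites with 10 reads, 77.9% with 30 reads, 89.8% where both intervals excluded 1, 74.5% with median-ratio scaling and 69.8% with totals without the storage and starch lists. That of line differences stayed inside its interval. Only 1 alternative set out beforehand changed the summed list ratios, members of category 0 to 2 alone. Under it, the ratios stayed inside their intervals in 124 cases and left them in 5. Its sums reuse reads of the main sums, so staying inside is no separate check. Under alternatives added later, 530 stayed, 101 left and 11 reversed. Reversals count ratios whose interval excluded 1; of ratios whose interval held 1, 3 and 43 changed sign.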

Other observations

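The tests of the authors' p-values, of a common factor and of fewer storage and inhibitor fragments, the merging of pairs, and sums over all members or without the member with most reads, were chosen only after the result was seen. Redox genes had summed heat ratios of 1.8 (1.32 to 2.49) in the sensitive and 3.27 (2.0 to 5.6) in the tolerant line over members with at least 10 reads, and 1.76 (1.39 to 2.24) and 1.91 (1.44 to 2.55) over all members. Intervals of 4 of 8 and 3 of 5 members held 1, and the copper chaperone and the dismutase gene LOC_Os03g22810, both miR398 targets, had the most reads among them. The basic globulin gene LOC_Os01g71090 had 0 reads in both controls, 19 in sensitive heat and 22 in tolerant heat. Squamosa promoter-binding-like genes under miR156 had 14, 85, 25 and 62 reads in sensitive control, sensitive heat, tolerant control and tolerant heat, over all sites. Their summed heat ratios were 2.29 (1.19 to 4.76) and 1.55 (0.85 to 2.93) over sites with at least 10 reads, the second with an interval that held 1, and 3.71 (2.1 to 7.08) and 1.76 (1.09 to 2.93) over all sites. Median-ratio scaling gave 2.03 (1.12 to 3.85) for the second, and without the site with most reads the first was 8.56 (2.16 to 74.2). Scarecrow-like genes under miR171 had summed ratios of 1.64 (1.21 to 2.26) and 1.14 (0.857 to 1.53) over sites with at least 10 reads, the second 1.5 (1.12 to 2.01) with median-ratio scaling.

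Genes of the heat-shock list had more fragments in heat in both lines, 1.88 (1.68 to 2.1) and 2.61 (2.29 to 2.98) times when summed over all its sites, with no read minimum, as are the values that follow. Fewer storage-protein and amylase-inhibitor fragments would raise every other value, but with both lists left out of the totals the ratios were 1.66 and 2.21, the lower of their lower bounds being 1.49, or 1.72 (1.53 to 1.93) and 2.26 (1.97 to 2.6) over members with at least 10 reads. Without the most abundant member, BIP1, that bound was 2.01 with all listed reads as totals, and over sites whose bases stand in no other listed gene it was 1.51, which argues against 1 member or shared reads as the whole cause. Only 2.25% of the list's reads lay at sites with a site p-value under 0.05, which argues against guidance by the paired miRNAs for most of these fragments. More heat-shock transcripts in heat may therefore be a candidate explanation, a hypothesis that these tables leave open, because they hold no transcript levels and each condition has 1 library.

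Sites of conserved miRNA families had heat ratios of 1.48 in the sensitive and 1.26 in the tolerant line when summed over all sites. Totals without the storage and starch lists move every log2 ratio by -0.18 and -0.24, and median-ratio scaling by -0.0035 and 0.39. Much of the second rise thus depends on the scaling, which can shrink or enlarge it. Of 58 family sites with at least 10 reads in the sensitive line, 27 were higher, 11 lower and 20 had an interval that held 1. Of 54 in the tolerant line, these were 23, 6 and 25. With totals without the storage and starch lists they were 24, 12 and 22, and 19, 8 and 27. With median-ratio scaling they were 26, 11 and 21, and 30, 3 and 21. One common factor, such as a better yield of cleavage products, was examined by family. Intervals excluded the summed ratio for 14 of 20 families in the sensitive line and 9 of 20 in the tolerant line. The family ratios thus differed by more than counting error. Those intervals leave out spread between libraries, so this cannot decide about a common factor. Family sites exceeded other sites outside the storage and starch lists by 0.41 in median log2 ratio in the sensitive line (bootstrap interval 0.13 to 1.07) and by 0.19 in the tolerant line (-0.16 to 0.87). In the tolerant line more fragments at all other sites cannot be told apart from more at family sites, as that interval holds 0. Heat itself stays untested as a cause, with 1 library per group.

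Pairs seen as 1 read in 1 library and none in the other were called as changed in the authors' deposited table, with p-values of at most 1.42e-06. A candidate explanation is that the authors' test took RPM values as if they were reads: a chi-square on the RPM values gave 58805 of 58805 deposited p-values within 1%, leaving out those too small for the comparison. No biological explanation was tested for this pattern.

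Called pairs with 0 reads in 1 library had reads in both once miRNAs and isoforms of a site were merged in 15.9%, 16.3%, 16.8% and 18.1% of cases, for the sensitive line, the tolerant line, controls and heat libraries. In the same order, the interval of the merged site held 1 for 91.2%, 93.8%, 94.7% and 95.0% of these called pairs. The site of NAC gene LOC_Os06g46270 at nucleotide 965 was given to different miR164 members in control and heat and had 173, 200, 142 and 134 reads when merged.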
